A study of Mus musculus with 34 samples.

How the data were processed

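Gene expression was measured on 34 one-colour Agilent arrays, 1 RNA sample per array, in 17 groups of 2 biological replicates from C57BL6/j mice of 6 to 8 weeks. Per the labels, Cy3-labelled RNA was made from 0.2 µg of total RNA with a linear amplification kit. Per the file headers, the arrays lay on 10 slides scanned on 5 days, and slide and day were used as batches.

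The deposited values are intensity. Per the file headers, the authors extracted the spots with Agilent Feature Extraction 9.5.3.1 (version 9.5 per the labels), which subtracts background and detrends each array. Each deposited file also holds other columns, 0 or 1 marks for spots that are well above background, saturated or non-uniform. The authors applied no scaling between arrays: the deposited series values equal the processed intensity of the scanner files at all 45018 spots, with a ratio of 1 throughout. The raw median intensity of each spot and of its local background is deposited too; the mean signal is not.

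Of the 45018 spots, 1639 were controls and 43379 were used, for 41174 probes. Spots marked as non-uniform or population outliers were left out, 32 to 274 per array, and replicate spots of a probe were averaged on the log2 scale. Probe names came from the platform accessions matched to mouse RefSeq annotation: 22951 probes by accession and 67 by symbol or synonym, while 18156 probes kept the identifier in the files. The files give no genome position for the probes and no position was assigned. A gene with several probes was represented by the probe with the highest mean signal over all arrays, which left 33370 gene names, 16398 of them with a symbol and 5325 with several probes.

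The log2 processed signal minus the array's 75th percentile (log2) is the normalized value used throughout. A gene was tested in a comparison when its probe was well above background on both arrays of at least 1 group entering it. Models were fitted with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8): 1 model for the 10 testis and Sertoli cell arrays in 5 groups, with 5 residual degrees of freedom, and 1 for the 24 tubule arrays in 12 groups, with 12. Moderated tests were two-sided and adjusted by the Benjamini-Hochberg method within each of the 15 comparisons, with a threshold of 0.05. A fold against a group that was not well above background on either array is given as a lower bound, computed against the lowest signal called well above background on those arrays.

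The gene lists, the comparisons, the rule for naming genes and the alternative settings were fixed before the data were examined, except for normexp on the median signal, the fits within single slides or days, and the comparison of untreated stages VII-VIII with IX-XII. The 21 lists hold 363 members, of which 343 were measured: Sertoli, spermatogonia, spermatocyte, spermatid, Leydig, peritubular myoid, macrophage and immune, endothelial and erythroid markers; retinoid metabolism and receptors; textbook retinoic acid targets; tight junction; adhesion and other junctions; stage-regulated and androgen-responsive Sertoli genes; cholesterol synthesis; lysosome and phagocytosis; interferon response; cell cycle; extracellular matrix; and immediate early and heat shock genes. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. A list is said to be called or not called by camera with the preset correlation, unless stated. Over all comparisons fry called 112 of 292 list tests and camera 51. For sorted WT cells against whole testes fry called 20 of 21 lists and camera 12. The named genes are Nanos3, Rara, Sox9, Stra8, Cyp26a1, Rarb and Cldn11 in every comparison, the 6 largest rises and 6 largest falls among genes past the threshold with a symbol, and up to 4 members of each list with the smallest adjusted p; a few genes that this rule names are not reported here. Genes called sorted-enriched are the 6904 that were at least 2-fold higher in sorted WT Sertoli cells than in whole testes at an adjusted p under 0.05.

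The comparisons were sorted WT Sertoli cells against whole testes, sorted knockout against sorted WT cells, cultured against sorted cells, retinoic acid (RA) against vehicle in culture, stage groups within each tubule arm, dnRARa against Venus over and within stages, the dnRARa-by-stage interaction, and Venus against untreated tubules. The alternatives were quantile and median scaling, normexp background correction of the median signal with an offset of 50 (chosen after the columns were seen), no detection filter or detection on every array, the mean of detected probes, 1 model for all arrays, only the arrays compared, an intensity trend, replicate, slide and scan-day blocks, a 2-fold minimum, and leaving out each array in turn. A rerun on the deposited series values was also among the alternatives, although these equal the processed signal. Counts over other splits of the arrays came from limma models of only the arrays split. For a stage difference these set 4 of the 8 arrays of an arm against the other 4, without terms for the stage groups, in 35 splits, so the real split gives another count there than the full model. For differences between arms, arrays were exchanged within stage groups and the stage groups were kept as terms, in 100 splits.

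The share of spots well above background ran from 54.89% to 74.42% per array, the 75th percentile of the signal from 750.9 to 2084, and at most 6 spots were saturated. Arrays carry no counts, so the number of arrays limits the precision. The procedure was tested on simulated data made from each gene's mean and residual SD in the fitted arrays, with 50 genes changed at each of 4 folds. Arrays and genes were drawn independently, whereas the dnRARa arrays correlated by replicate at 0.44 to 0.7 between stage groups. The rates that follow therefore leave out effects of slide and replicate. For RA against vehicle it recovered 36% of 2-fold and 64% of 4-fold changes, with 5 false calls among 109. For dnRARa against Venus over the stages it recovered 80% of 2-fold changes, with 8 false calls among 178; within stages VII-VIII alone it recovered 52%, and for the interaction 40%.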

Results

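The series profiled mouse testis material on 34 arrays in 17 groups of 2 biological replicates. There were 2 arrays each of whole testes, of Sertoli cells sorted by FACS from wild-type (WT) testes, of Sertoli cells sorted from Nanos3-knockout (N3KO) testes, and of primary Sertoli cells cultured with vehicle or with retinoic acid (RA) for 24 hours, at 1 mM per the labels; the unit could not be checked in the files. Sertoli cells are the somatic cells of the seminiferous tubule that nurse the germ cells; the labels do not state the marker used to sort them. The other 24 arrays were of seminiferous tubules in 4 stage groups of the epithelial cycle (I-III, IV-VI, VII-VIII and IX-XII, where the sample titles write VI-VIII for the third group and its source names VII-VIII), untreated or 5 days after injection of a lentivirus into the testis. The virus carried the fluorescent protein Venus, as control, or dnRARa, a dominant negative form of retinoic acid receptor alpha. From 54.89% to 74.42% of spots per array were well above background, and replicate arrays correlated across genes at r from 0.9687 to 0.9992, the lowest being the knockout cells. Values are log2 signals relative to the array's 75th percentile, every group mean is of 2 arrays unless stated, and each difference is given on the log2 scale with its standard error (SE) or as a fold. Genes named as the largest rises or falls are those by fitted difference; in many of them 1 group lay at or near background, so no order among them is implied.

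The comparison of sorted WT Sertoli cells with whole testes asked which transcripts the sort enriched and which other cells it left in. From the Sertoli list Gata4, a transcription factor of gonadal somatic cells, was 2.09 higher (SE 0.19) and the intermediate filament gene Vim 2.64 (SE 0.13). Leydig and endothelial transcripts rose as well, so these 2 rises need not come from Sertoli cells. Rhox5 was at 2.73 in whole testes and 3.03 in sorted cells. Gdnf was at -5.1 in whole testes and -6.15 in sorted cells, where neither array was above background. Cldn11, the tight junction protein of Sertoli cells, was 0.45 higher (SE 0.18, adjusted p = 0.0485), while Sox9 differed by 0.33 (SE 0.13) and did not pass (adjusted p = 0.0508). Transcripts of Leydig cells, the steroid-making cells between the tubules, rose further: Agt by 4.74 (SE 0.14), Hsd3b6 by 4.63 (SE 0.26), and Insl3, a Leydig hormone, by 2.44 to a mean of 9.71. Germ cell transcripts fell. The meiosis inducer Stra8 was lower by 3.45 (difference -3.45, SE 0.11), the RNA-binding protein gene Nanos3 by 5.12 (-5.12, SE 0.36), the spermatocyte surface gene Tex101 by -5.05 and the sperm glycolytic enzyme gene Gapdhs by -3.76. The largest rises were of Fos (at least 91-fold), Zfp979, Cxcl10, Hspb8, Olfr78 and Ecrg4, and the largest falls of Pax1, Gad2, Lypd10, B4galnt4, Bmp8b and Prss50. Cyp26a1 (0.44, adjusted p = 0.532) and Rarb (1.09, adjusted p = 0.158) did not pass, and Rara, at or near background, was not tested.

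By list, 13 of 23 Sertoli genes rose and 1 fell (12 and 1 adjusted over the list alone), a shift that camera did not call (adjusted p = 0.057). All 23 spermatid genes and 18 of 19 spermatocyte genes fell, and 10 of 13 spermatogonial genes fell (6 to 11 over 4 scalings) while 1 rose; camera called all of these, with adjusted p = 0.348, 0.315 and 0.315 with an estimated correlation. Of 11 Leydig genes, 10 rose (median 4.26, adjusted p = 0.000704, and adjusted p = 0.363 with an estimated correlation). Of 10 endothelial genes, 9 rose, among them Cdh5 by 4.02 and Emcn by 4.06 (camera adjusted p = 0.00974, and adjusted p = 0.547 with an estimated correlation). Of 8 peritubular myoid genes, 5 rose and 2 fell, and of 13 macrophage and immune genes 5 rose and 2 fell. Camera called neither list (adjusted p = 0.119 and 0.252). The same counts stood adjusted over each of these lists alone, except that 4 immune genes rose. Among 3 erythroid genes Slc4a1 fell (-0.72) and none passed over the list alone.

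Several functional groups moved together with those markers of other cell types. The immediate early and heat shock list had 16 of 17 genes higher and 1 lower, with Junb up 4.48 and Jun 3.91, and the interferon response list 20 of 22, with Bst2 up 4.06 and B2m 3.85. Camera called both (camera adjusted p = 0.00068 and 1.76e-05, and adjusted p = 0.462 and 0.0741 with an estimated correlation). The lysosome list had 18 of 21 higher, with Ctsh and Lamp2 up 4.41 and 3.97, and the cholesterol synthesis list 12 of 18 higher and 2 lower, with Msmo1 up 4.43 (adjusted p = 0.363 and 0.547 with an estimated correlation, against 5.51e-05 and 0.0064 with the preset value). Of 21 cell cycle genes 15 were lower and 4 higher, 16 and 4 adjusted over the list alone, with Cdc20 at -3.02 (adjusted p = 0.0064, and adjusted p = 0.363 with an estimated correlation). Of 18 adhesion genes 11 rose and 2 fell and of 16 stage-regulated Sertoli genes 11 rose and 1 fell (adjusted p = 0.315 and 0.348 with an estimated correlation, against 0.0223 and 0.0292). The lists of retinoid metabolism and receptors (7 higher, 6 lower of 18, with the retinaldehyde reductase gene Dhrs3 up 3.64 and the dehydrogenase gene Aldh1a1 up 3.37), RA targets (5 higher, 4 lower of 12), androgen-responsive genes (3 higher of 8) and extracellular matrix (8 higher, 2 lower of 14) were not called by camera (adjusted p = 0.5, 0.563, 0.0896 and 0.113). Of 17 tight junction genes 7 rose and 5 fell (6 and 5 over the list alone, and 1 to 5 lower over 4 scalings), with a median of -0.12 that turned to 0.25 under normexp and a mean of 0.47.

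In all, 18149 of 22910 tested genes passed in this comparison, 8793 higher and 9356 lower. Both groups lay on 1 slide. Median scaling moved the all-gene median from -0.062 to -0.193.

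**Figure D1:**
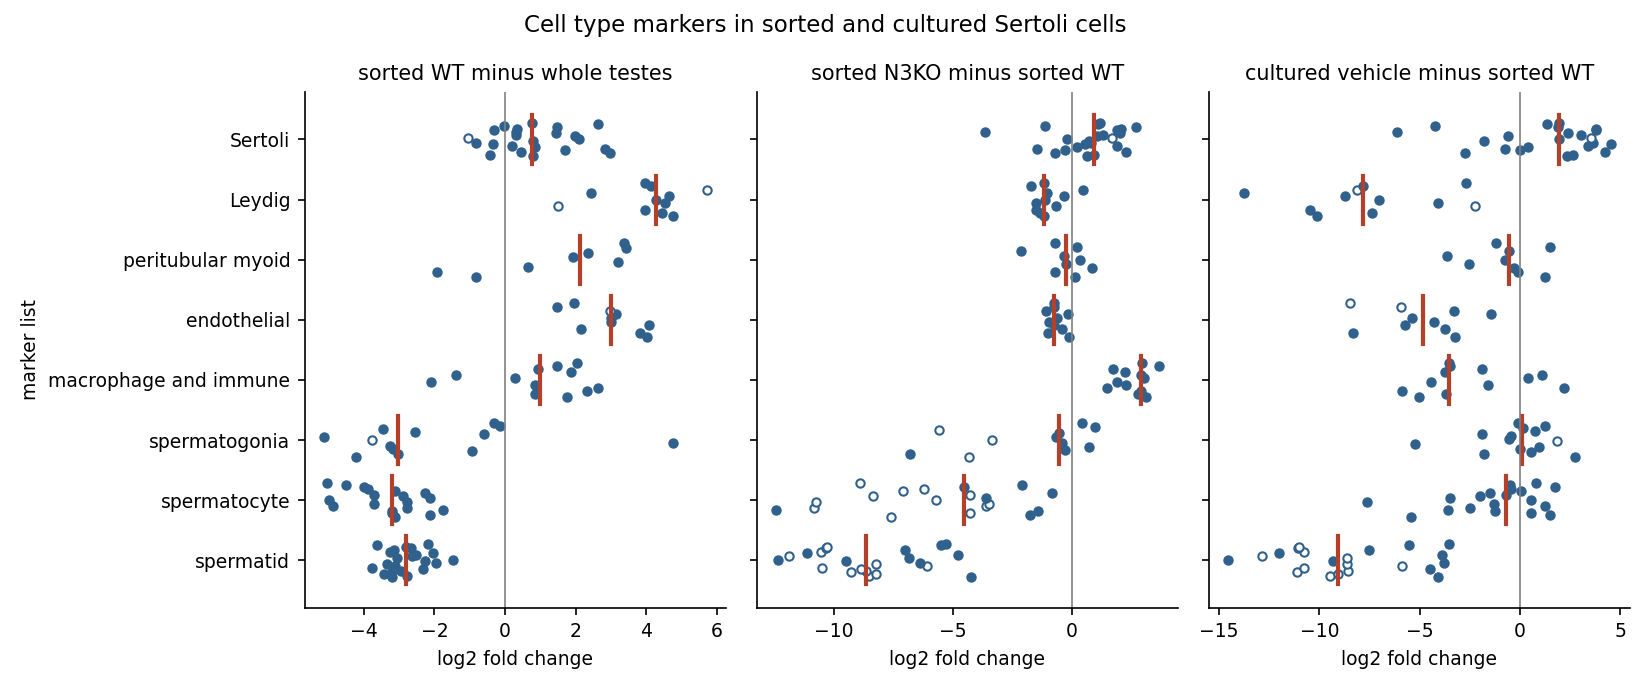
Log2 fold changes (horizontal axes) of the tested genes of 8 marker lists (vertical axis) in sorted WT cells against whole testes, knockout against WT sorted cells, and cultured against sorted WT cells. Each point is a gene (open where 1 of the groups was not above background on either array, so that the value is no measured fold), and the red bar is the list's median; the Leydig median is 4.26 in the left panel, -1.15 in the middle panel and -7.84 in the right panel.

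The comparison of sorted cells from knockout and WT testes asked how their transcripts differ when germ cells are missing. Nanos3 is needed for the survival of germ cell precursors. Germ cell transcripts were far lower in the knockout cells. Protamine 2 (Prm2) was lower by 12.36 (-12.36, SE 0.31) from a WT mean of 7.9, the transition protein gene Tnp1 by -11.11 (SE 0.26) from 7.43, the helicase gene Ddx4 by -6.78 (SE 0.2), and Stra8 was at least 43.4-fold lower. Nanos3 itself was at least 3.44-fold lower, although its difference was 0.13 under normexp. Among Sertoli genes Sox9 was higher by 2.07 (SE 0.13), Cldn11 by 2.29 (SE 0.17) and the transferrin gene Trf by 2.72 (SE 0.28), while the androgen-regulated homeobox gene Rhox5 was lower (-3.66, SE 0.39). The RA-degrading enzyme gene Cyp26b1 was 4.24 higher (SE 0.27), whereas Cyp26a1 (-0.67, adjusted p = 0.401) and Rarb (1.46, adjusted p = 0.1) did not pass.

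All 23 spermatid and all 19 spermatocyte genes fell (camera adjusted p = 1.31e-17 and 2.58e-11, and adjusted p = 0.146 for both with an estimated correlation). Of 11 spermatogonial genes 6 fell and 3 rose, with a median of -0.53 that turned to 0.26 under normexp and 0.04 under median scaling. Of 23 Sertoli genes 12 rose and 1 fell (13 and 2 over the list alone; adjusted p = 0.00466, and 0.368 as adjusted p with an estimated correlation). Of 18 tight junction genes 14 rose, among them Jam2 by 2.05 and Jam3 by 1.42, and of 18 adhesion genes 9 rose and 1 fell (adjusted p = 0.146 and 0.244 with an estimated correlation, against 0.000438 and 0.036). Macrophage and immune genes rose in 12 of 13 cases, the antigen-presenting H2-Ab1 by 2.93 and the leukocyte gene Ptprc by 3.65 (adjusted p = 0.000829, and adjusted p = 0.237 with an estimated correlation). Lysosome genes rose in 8 of 21 cases and fell in 1, Ctss leading with 4.03 (adjusted p = 0.00973, and adjusted p = 0.506 with an estimated correlation). The Leydig list had 5 of 11 genes lower, with Star at -1.15 and Insl3 at -1.05, and was not called (adjusted p = 0.0761). Over 4 scalings 7 to 19 lysosome genes and 8 to 14 adhesion genes were higher and 2 to 5 Leydig genes lower. The largest rises were of Spsb4 (at least 52.6-fold), Wfdc18, Adgrg2, Bcan, Fam171b and Hrk, and the largest falls of Ldhc, Prm2, Smcp, Cabs1, Cox8c and Gykl1, genes of meiotic and postmeiotic germ cells in the case of Ldhc, Prm2 and Smcp; Ldhc was above background on 1 of 2 knockout arrays, and Smcp, Cabs1, Cox8c and Gykl1 on neither.

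Of 21477 genes tested, 10481 passed, 5639 higher and 4842 lower. Of the genes that passed, 53.8% were higher, a share that went to 64.7%, 63.3% and 77.1% under normexp, quantile and median scaling, which moved the median of all genes from 0.073 to 0.27, 0.228 and 0.641, and a model of these 4 arrays alone called 4174. The WT cells lay on 1 slide and the knockout cells on another of the same day, so genotype and slide cannot be told apart. The sorted WT cells also held transcripts of other cells, with Tnp1 at 7.43 and Insl3 at 9.71, against -3.68 and 8.66 in knockout cells. Higher Sertoli transcripts in knockout cells therefore cannot be told apart from a larger share of Sertoli cells among those sorted.

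Cultured Sertoli cells with vehicle were compared with sorted WT cells to see how the cells of these preparations differed. Among Sertoli genes Sox9 was higher in culture by 3.79 (SE 0.13), Cldn11 by 4.21 (SE 0.18) and Dmrt1, a transcription factor of the male gonad, by 4.51 (SE 0.23). Leydig, spermatid and endothelial transcripts were far lower: Insl3 by -13.76 (SE 0.16) and the endothelial claudin gene Cldn5 by -8.33 (SE 0.56). Prm2 went from 7.9 to background, with 1 of 2 cultured arrays above it. Cyp26a1 was at least 19.7-fold lower and Dhrs3 lower by -6.21 (SE 0.12), both genes that RA induces, and Rhox5 was lower by -6.14 (SE 0.39). Rara was at least 3.18-fold higher, while Nanos3 (-0.54), Stra8 (0.14) and Rarb (-0.51) did not pass (adjusted p = 0.212, 0.295 and 0.494).

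All 23 spermatid genes, 10 of 11 Leydig genes and all 10 endothelial genes fell (adjusted p = 0.187, 0.402 and 0.638 with an estimated correlation, against 1.5e-09, 0.000223 and 0.00561 with the preset value). Of 23 Sertoli genes 16 rose and 4 fell, of 18 tight junction genes 14 rose and 1 fell, and of 19 adhesion genes 11 rose and 3 fell (adjusted p = 0.388, 0.174 and 0.182 with an estimated correlation, against 0.00111, 4.98e-05 and 0.00858). Cell cycle genes rose in 20 of 21 cases, Ccna2 by 4.91 and Mcm4 by 2.81, and matrix genes in 13 of 17 with 1 lower, Mmp2 rising by 5.96 (adjusted p = 0.182 and 0.174 with an estimated correlation, against 7.54e-08 and 0.000212). All these counts were the same adjusted over the list alone, except that 14 matrix genes rose. The largest rises were of the neurofilament genes Nefl and Nefm, Ankrd1, Dner, Rprm and Bcan, and the largest falls of Sult1e1, Hsd3b2, Prm2, Jak3, Insl3 and Bhmt. The Jak3 probe reads a gene next to Insl3, and which of the 2 transcripts it measured was not resolved.

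Of 22436 genes 16781 passed, 7197 higher and 9584 lower. Of the genes that passed, 42.9% were higher, a share that became 50.2%, 53.2% and 66.3% under normexp, quantile and median scaling, with all-gene medians of -0.208, -0.056, 0.105 and 0.717. The cultured cells lay on a slide and day of their own, so culture and batch cannot be told apart. The sorted cells also held more transcripts of other cells, with Insl3 at 9.71 against -4.05 and Tnp1 at 7.43 against -4.6 in culture. Higher Sertoli transcripts in culture therefore cannot be told apart from a larger share of Sertoli cells.

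RA was added to cultured Sertoli cells to find the genes that respond to it. Its classical targets rose steeply: Cyp26a1, whose enzyme degrades RA, by at least 663-fold, Dhrs3 by 5.21 (SE 0.11), Stra8 by 3.92 (SE 0.11) and the receptor gene Rarb by 3.48 (SE 0.64, adjusted p = 0.0255). Some germ cell transcripts were present in the vehicle cultures, with Ldhc at 3.39, Ddx4 at 0.58 and Stra8 at -0.03, while the spermatid gene Tnp1 was at -4.6. Which cells of the culture raised Stra8 is therefore not known. The nuclear receptor gene Nr0b1, a repressor of steroidogenic genes, rose by 6.48 (SE 0.16), followed by Ntn5, Asic2 and Car11, and the Sertoli transcription factor gene Gata1 rose by 3.15 (SE 0.19). The gap junction gene Gja1 fell by 1.69 (SE 0.15), the chemokine gene Cxcl12 by 1.85 (SE 0.2) and Gdnf, the growth factor for spermatogonial stem cells, by 0.84 (SE 0.13). The largest falls were of Crct1, Bcl2l10, Rspo2, Gjb5, Fam169b and Elovl2, the latter by 2.52 (SE 0.23). Sox9 (0.48, adjusted p = 0.0878), Rara (0.2), Cldn11 (0.11) and Nanos3 (-0.21) did not pass (adjusted p = 0.789, 0.858 and 0.864 for the latter genes).

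Of 11 tested RA targets 9 rose, 10 adjusted over the list alone (camera adjusted p = 4.54e-17, and adjusted p = 0.00514 with an estimated correlation). This was 1 of 51 list calls among 292 tests over all comparisons with the preset correlation, and the only 1 that held with an estimated correlation. Of 18 genes of retinoid metabolism and receptors 7 rose and 2 fell, among them Rdh10 and Cyp26b1, up 4.14 and 3.76 (adjusted p = 0.000121, and adjusted p = 0.0517 with an estimated correlation). In the spermatogonial list Stra8 and Uchl1 rose, and in the interferon list Oasl2 rose (1.53) while the RNA sensor gene Ddx58 fell (-1.22), with 2 higher and 5 lower of 21 over the list alone (adjusted p = 0.234 and 0.168 with an estimated correlation, against 0.0474 and 0.0161). Of 23 Sertoli genes Gata1 and Wt1 rose and Gdnf fell, and of 20 adhesion genes 2 rose and 3 fell, with neither list called (adjusted p = 0.741 and 0.164). None of the tested genes of the cell cycle, cholesterol, lysosome, matrix, immediate early, endothelial, peritubular, macrophage, Leydig or spermatid lists passed over all genes by limma (2 Leydig genes were lower over the list alone).

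In all, 1099 of 20078 genes passed, 712 higher and 387 lower, and 3593 had an unadjusted p under 0.05. It was 363 to 381 without any 1 of the 4 arrays, 562 with normexp, 714 without a detection filter, and 7196 in a model of these 4 arrays alone. The main model shares its spread with the testis and sorted cell arrays. Across genes the SD of the difference between replicates was 0.1235 with vehicle and 0.1043 with RA, against 0.6404 in knockout cells. A gene that did not pass here is therefore not shown to be unchanged by RA. All 4 arrays shared 1 slide, and normexp moved the all-gene median from 0.009 to -0.107.

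**Figure D2:**
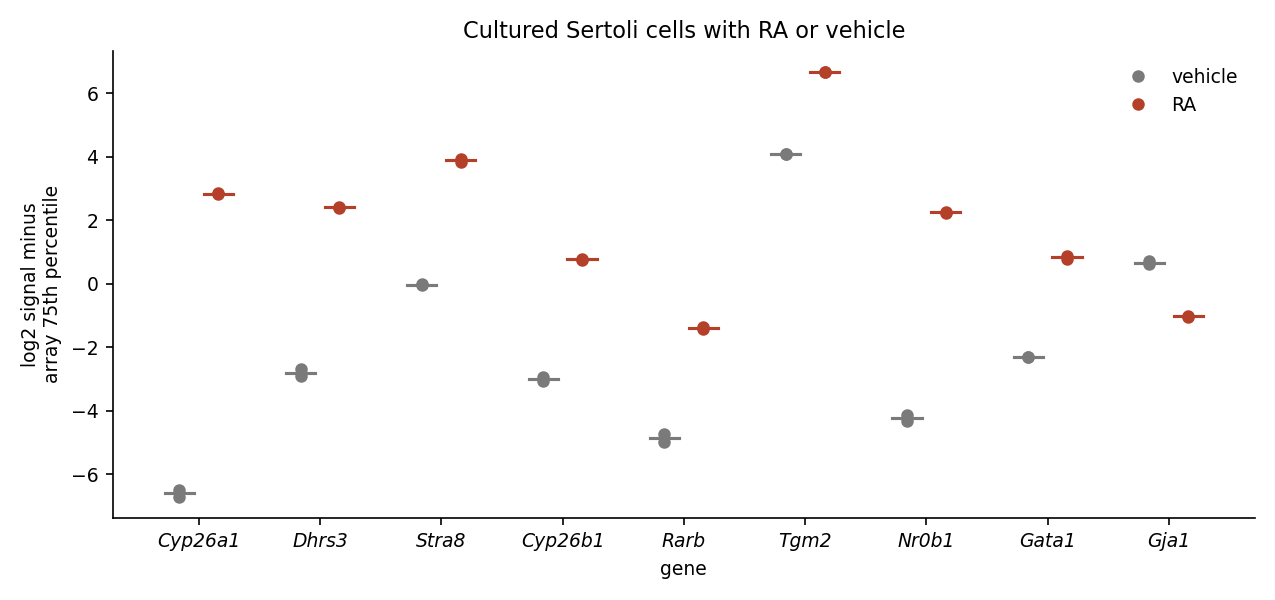
Log2 signal relative to the array's 75th percentile (vertical axis) of 9 genes (horizontal axis) in cultured Sertoli cells with vehicle (grey) or RA (red); points are the 2 arrays of a group and bars their mean. Cyp26a1 rose from a mean of -6.61, where neither array was above background, to 2.83, and Gja1 went from 0.66 to -1.03.

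Untreated tubules of 4 stage groups were compared to find the genes that change along the epithelial cycle. Stra8 was highest in stages VII-VIII, at 5.54 ± 0.11 (SD, n = 2), against 1.11 ± 0.2 in IV-VI, and over both later groups it was 2.76 higher than over both earlier ones (SE 0.3). Cyp26a1 had a similar profile, with -1.75 ± 0.58 in VII-VIII and -2.46 ± 0.38 in IX-XII, against -5.76 ± 0.53, below background, in IV-VI; it passed between later and earlier stages, where 1 of 4 earlier arrays was above background, so no fold is given. The aquaporin gene Aqp8 was lower in the later stages (-2.3, SE 0.22), with 4.72 ± 0.42 in IV-VI and 1.86 ± 0.26 in IX-XII, and Rhox5 was at 4.23 ± 0.27 in IV-VI and 1.31 ± 0.05 in IX-XII (SD, n = 2). The genes with the strongest evidence of any stage difference were Alas2, Ssxb1, Gsc, Ssxb2, Plk1 and Fam78a; Plk1, a mitotic and meiotic kinase, was at 1.79 ± 0.05 in VII-VIII and between 5 and 5.8 in the other groups. The plasminogen activator gene Plat (1.92, SE 0.15), Gata1 (1.04, SE 0.14) and the retinol dehydrogenase gene Rdh10 (2.41, SE 0.26) were higher in the later stages. Sox9 (-0.01), Cldn11 (0) and Nanos3 (1.27, SE 1.2) did not pass between early and late stages (adjusted p = 0.956, 0.995 and 0.397), and Rara and Rarb were at background.

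No list was called by camera between later and earlier stages. Cell cycle genes came closest, with 12 of 21 lower and 1 higher (median -0.28, adjusted p = 0.0614), Ccnb1 at -1.41 and Mcm3 at -0.78. Of 10 RA targets 5 were higher and 1 lower, and of 15 genes of retinoid metabolism and receptors 5 were higher and 2 lower (adjusted p = 0.416 and 0.929). Of 16 adhesion genes 6 were higher and 7 lower, with the ectoplasmic specialization genes Espn and Eps8 at -1.39 and -0.99; the list's median was -0.2 and its mean 0.03, and 4 to 7 were lower over 4 scalings. These counts were the same over the lists alone. Of 14 stage-regulated Sertoli genes 4 were lower and 1 higher, and of 18 cholesterol genes 5 were higher and 3 lower, with Insig1 up 1.89. Of 23 spermatid genes 7 were higher and 4 lower, with Tnp2 up 1.35, the acrosomal gene Spaca1 down (-0.98) and a median of 0.08 that turned to -0.04 under normexp and -0.1 under quantile scaling; over 4 scalings 3 to 8 were lower. The largest rises toward the later stages were of Col15a1, Abra, Col26a1, Pax1, Tm4sf4 and Trim42, and the largest falls of Ssx9, Ssxb1, Ssxb2, Gabra5, Chac1 and Il20ra.

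Any stage difference passed in 13491 of 19495 genes, and later against earlier stages in 9843, 5317 higher and 4526 lower; 2041 of 4999 sorted-enriched genes passed, 957 higher and 1084 lower. Replicate numbers paired the arrays of this arm (correlations from 0.2 to 0.7 between stage groups), and with replicate within the arm as a block 11873 passed (10550 with 1 replicate term shared by all arms). Slides of these arrays held 1 stage group each, except that VII-VIII and IX-XII shared a slide, so within this arm stage group and slide were not separated. The Venus and dnRARa slides each held all 4 stage groups. Across genes, the untreated stage difference correlated with that of Venus tubules at r = 0.883 (19340 genes) and with that of dnRARa tubules at r = 0.846. Of genes passing in both untreated and Venus tubules 3778 were higher and 3740 lower in both, against 38 and 18 with opposite directions. Normexp moved the all-gene median from 0.04 to 0.18 and gave 5380 higher and 2766 lower, and quantile scaling gave 5062 and 5047.

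The same stage comparison was made within each virus arm. In Venus tubules Stra8 (2.66, SE 0.31), Cyp26a1 (4.42, SE 0.51, with 3 of 4 earlier arrays above background), Plat (2.75, SE 0.15) and Gata1 (1.71, SE 0.14) were higher in the later stages and Aqp8 was lower (-4.31, SE 0.22). In dnRARa tubules Stra8 (2.95, SE 0.31), Plat (1.57, SE 0.15) and Gata1 (0.6, SE 0.14) were higher. Cyp26a1 passed there too, but only 1 of 4 earlier arrays was above background, and Rarb passed but was above background on both arrays of IX-XII and on none of the other stage groups, so no fold is given for either. Sox9, Cldn11, Nanos3 and Rara did not pass in either arm (for Rara 0.22 with adjusted p = 0.442 in Venus and 0.47 with adjusted p = 0.0902 in dnRARa tubules). The steepest changes were of Col15a1, Trim42, Abra, Unc93a and Prss52 upward and of Ssxb1, Ssxb2, Ssx9, Sostdc1 and Pkib downward in both arms. Hemgn was among the rises and Il20ra among the falls of the Venus arm, and the lipid droplet gene Cidea (5.26) and Golga7b (-3.82) were among those of the dnRARa arm.

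Cell cycle genes were lower in the later stages in 12 of 21 cases and higher in 1 in Venus tubules (13 and 2 over the list alone; median -0.46, adjusted p = 0.000922, and adjusted p = 0.433 with an estimated correlation). The list medians were -0.52 and -0.44 on the slides of replicates 1 and 2. In dnRARa tubules 11 were lower and 6 higher, and the list was not called (adjusted p = 0.196; slide medians -0.35 and -0.35). Sertoli genes were lower in 11 of 23 cases and higher in 1 in Venus tubules, and 6 and 1 in dnRARa tubules, without a call in either (adjusted p = 0.136 and 0.204). Over 4 scalings 6 to 11 of them were lower in Venus and 2 to 7 in dnRARa tubules. The immediate early gene Nr4a1 was lower in both (-4.26 and -3.66), and the junction gene Jup was higher in both (4.3 and 3.04).

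In Venus tubules 10751 of 23585 genes passed (5069 higher, 5682 lower), and with slide as a block 11349; in dnRARa tubules 9833 of 23424 passed (5228 higher, 4605 lower), and with slide as a block 10533. Within the single slides, at 4 arrays each, limma called 419 and 62 genes in Venus tubules and 0 and 0 in dnRARa tubules, where 2908 and 3654 had an unadjusted p under 0.05. These models, with 2 residual degrees of freedom, had no terms for single stage groups. Differences between stage groups on the same side added to the residual spread, so fewer genes could pass. Across genes, which are not independent replicates, the differences on both slides of an arm correlated at r = 0.931 (rho 0.88) and 0.905 (rho 0.854). Normexp moved the all-gene median of the Venus difference from -0.037 to 0.1.

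Tubules with dnRARa were compared with Venus tubules over the 4 stage groups to find what blocking the receptor changed. Cyp26a1 (-1.31, SE 0.36, adjusted p = 0.0294, above background on 5 of 8 dnRARa and 7 of 8 Venus arrays), the transglutaminase gene Tgm2 (-0.58, SE 0.11) and Gata1 (-0.77, SE 0.1), which RA raised in culture, were lower. Inha, the inhibin alpha subunit made by Sertoli cells, was lower (-1.1, SE 0.1), as were the tight junction genes Ocln (-1.67, SE 0.19, above background on 6 of 8 dnRARa arrays) and Cldn3 (-1.11, SE 0.18). Aqp8 was 1.99 higher (SE 0.16) and Rhox5 0.71 (SE 0.08). Stra8 differed by 0.1 (SE 0.22, adjusted p = 0.826), Sox9 by -0.03, Cldn11 by 0.13 and Nanos3 by 0.41, none of which passed (adjusted p = 0.878, 0.208 and 0.815). Rarb, above background on 2 of 8 dnRARa and 1 of 8 Venus arrays, did not pass either (adjusted p = 0.0771). Rara read 0.65 higher (SE 0.15, adjusted p = 0.0108); whether its probe also reads the dnRARa transcript is not known. The largest rises were of Smg8, Itgax, Spink8, Ptpru, Aqp8 and the fatty acid elongase gene Elovl3, and the largest falls of Cidea (-3.57), Sowahd, Olig1, Tmem255a, Oit3 and the glycogen-binding protein gene Stbd1.

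Of 9 peritubular myoid genes, markers of the contractile cells around the tubule, 5 were lower (7 over the list alone), with Myh11 at -0.63 and Cnn1 at -0.67 (median -0.47, adjusted p = 1.58e-05, and adjusted p = 0.343 with an estimated correlation). The list's medians were -0.72 and -0.3 on the replicate 1 and replicate 2 slides. The Leydig list had a median of -0.43, with 1 of 10 genes lower, Cyp11a1 at -0.97 (adjusted p = 0.00972), and was not called (adjusted p = 0.216). Immediate early and heat shock genes were higher in 5 of 17 cases (9 over the list alone), Egr1 by 1, and Fos was above background on 7 of 8 dnRARa and 1 of 8 Venus arrays (list median 0.33, 0.15 and 0.46 on these slides; adjusted p = 0.0118, and adjusted p = 0.49 with an estimated correlation). Their median was 0.13 under normexp, and as few as 1 passed over 4 scalings. Of 12 RA targets 4 were lower and none higher (2 higher over the list alone), and of 19 genes of retinoid metabolism and receptors 4 were lower and 1 higher (5 and 3 over the list alone), with no call (adjusted p = 0.163 and 0.493). Of 17 tight junction genes 4 were lower (Ocln, Cldn3, Cldn7 and F11r), of 23 Sertoli genes 5 were higher and 4 lower, of 8 androgen-responsive genes 3 were higher and 2 lower, with Tubb3 at -0.75 and Eppin at 0.44, and of 19 spermatocyte genes 3 were higher (Sycp3, Sycp2 and Hormad1). Adjusted over the list alone, 1 tight junction gene was higher and 4 lower, 5 Sertoli genes higher and 6 lower, 4 androgen-responsive genes higher and 2 lower and 4 spermatocyte genes higher. None of these lists was called (adjusted p = 0.0971, 0.518, 0.507 and 0.216). The median and mean of the androgen-responsive list differ in sign (0.14 and -0.02).

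In all 2964 of 24116 genes passed, 2005 higher and 959 lower. The share higher was 67.6%, and 54% with median scaling (1541 and 1313), 57.6% with quantile scaling (1605 and 1183) and 56.6% with normexp. Over sorted-enriched genes 879 of 6119 passed, 411 higher and 468 lower. Both arms of a replicate were scanned on the same day on separate slides. Within an arm the arrays of a replicate shared a slide. Replicate differences correlated between stage groups at 0.44 to 0.7 with dnRARa and at 0.05 to 0.47 with Venus. The model took these arrays as independent, so the count may overstate how many genes differ. A scan-day block does not remove a correlation that belongs to the slide of an arm. With scan day as a block 3492 genes passed, within the replicate 1 slides 765 (682 higher, 83 lower) and within the replicate 2 slides 1615 (1170 higher, 445 lower). The fold changes of both pairs of slides correlated across genes at r = 0.515 (rho 0.447). The count was 731 with normexp and 4648 in a model of these 16 arrays alone.

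Within stage groups the dnRARa difference was measured with 2 arrays per arm. In IX-XII large rises were of Aqp8 (6.35, SE 0.31), from a Venus mean of -2.16 to 4.18, and of Mical2, an actin-oxidizing enzyme gene (5.09, SE 0.31). Ptpn7, Gsta2, Fam110c (at least 5.55-fold) and Elovl3 (at least 7.45-fold) were higher too. Untreated tubules of these stages had Aqp8 at 1.86 and Mical2 at -4.32. Gata1 (-1.69, SE 0.2), Inha (-1.01, SE 0.2) and the largest falls, Olfr340, Stbd1, Plekhs1, Foxb2, Anxa9 and Esyt3, were lower there, while Rhox5 was 1.53 (SE 0.16) and the cyclin gene Ccnb1 1.06 (SE 0.16) higher. In VII-VIII Inha (-1.72, SE 0.2), Cldn3 (-2.12, SE 0.36), Ocln (above background on 1 of 2 dnRARa arrays) and Gata1 (-0.96, SE 0.2) were lower. The largest falls there were of Sowahd, Olig1, Tmem255a, Stbd1, Gpr149 and Helt (Gpr149 read 0.19 higher with normexp), with Ccl3 (at least 8.12-fold), Cep20, Defa23, Chst8, S100b and Cyp2b9 as the largest rises. In IV-VI Cidea (above background on 1 of 2 dnRARa arrays), Sowahd (at least 16.1-fold), Tmem255a, Olig1, Oit3, Anxa13, Inha (-1.02, SE 0.2) and the late spermatid genes Tnp2 (-2.6, SE 0.33) and Prm1 (-1.49, SE 0.24) were lower and Grm6, Smg8, Clic6, Hacl1, Runx2 and Glipr1l2 higher. The replicate 2 dnRARa array of IV-VI had 60.58% of spots well above background, the lowest share among the virus arrays. Its lowest signal well above background was -5.22, so detection and lower bounds in this group depend on it. In I-III only 2 transcripts passed, both known by platform identifiers alone, AV046780 (1.86) and NAP029548-1 (1.48); they fall outside the naming rule and were chosen after their values were seen.

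Cyp26a1 was lower by -2.14 (SE 0.72) in IX-XII and -1.94 (SE 0.72) in VII-VIII without passing (adjusted p = 0.119 and 0.256), and Stra8 differed by -0.08, -0.01, 0.31 and 0.18 from I-III to IX-XII, also without passing. The peritubular myoid list was called lower in all 4 stage groups, with medians of -0.21, -0.51, -0.62 and -0.48 and adjusted p = 0.00195, 0.00687, 0.000197 and 0.00426 (adjusted p = 0.615, 0.689, 0.363 and 0.379 with an estimated correlation). Its genes passing over all genes were 0, 1, 0 and 1 (0, 4, 2 and 2 over the list alone). In VII-VIII camera also called the tight junction list lower, with Ocln and Cldn3 passing among 17 genes and 4 over the list alone. It called the Leydig list lower as well, with none of 9 passing and 1 over the list alone (adjusted p = 0.363 and 0.549 with an estimated correlation, against 0.00376 and 0.00545). Cell cycle genes were called lower in IV-VI (2 of 21 lower, 5 over the list alone) and higher in IX-XII (2 higher, 3 over the list alone), with adjusted p = 0.0104 and 0.0262 (adjusted p = 0.689 and 0.379 with an estimated correlation). Immediate early genes were called higher in I-III and VII-VIII (adjusted p = 0.615 and 0.549 with an estimated correlation, against 0.000338 and 0.0424), with 0 passing over all genes by limma in either and 1 and 0 over the list alone. In IX-XII their median of 0.34 turned to -0.27 under normexp. Counts of genes were 2 of 22327 in I-III (1542 at an unadjusted p under 0.05), 757 of 22392 in IV-VI (347 higher, 410 lower), 356 of 23108 in VII-VIII (174 higher, 182 lower) and 1085 of 23097 in IX-XII (736 higher, 349 lower). The share higher went from 48.9% to 25.4% in VII-VIII and from 67.8% to 51.5% in IX-XII under normexp. Counts were 26, 934, 499 and 1302 with scan day as a block. Leaving out 1 array moved them to between 17 and 265, 38 and 737, 84 and 535, and 322 and 629, and a model of the 4 arrays alone called 0, 1, 0 and 1030, with 2296, 4486 and 2658 genes at an unadjusted p under 0.05 in the earlier 3 groups. Median scaling moved the all-gene median from 0 to -0.112 in I-III, and normexp from 0.05 to -0.203 in IX-XII.

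**Figure D3:**
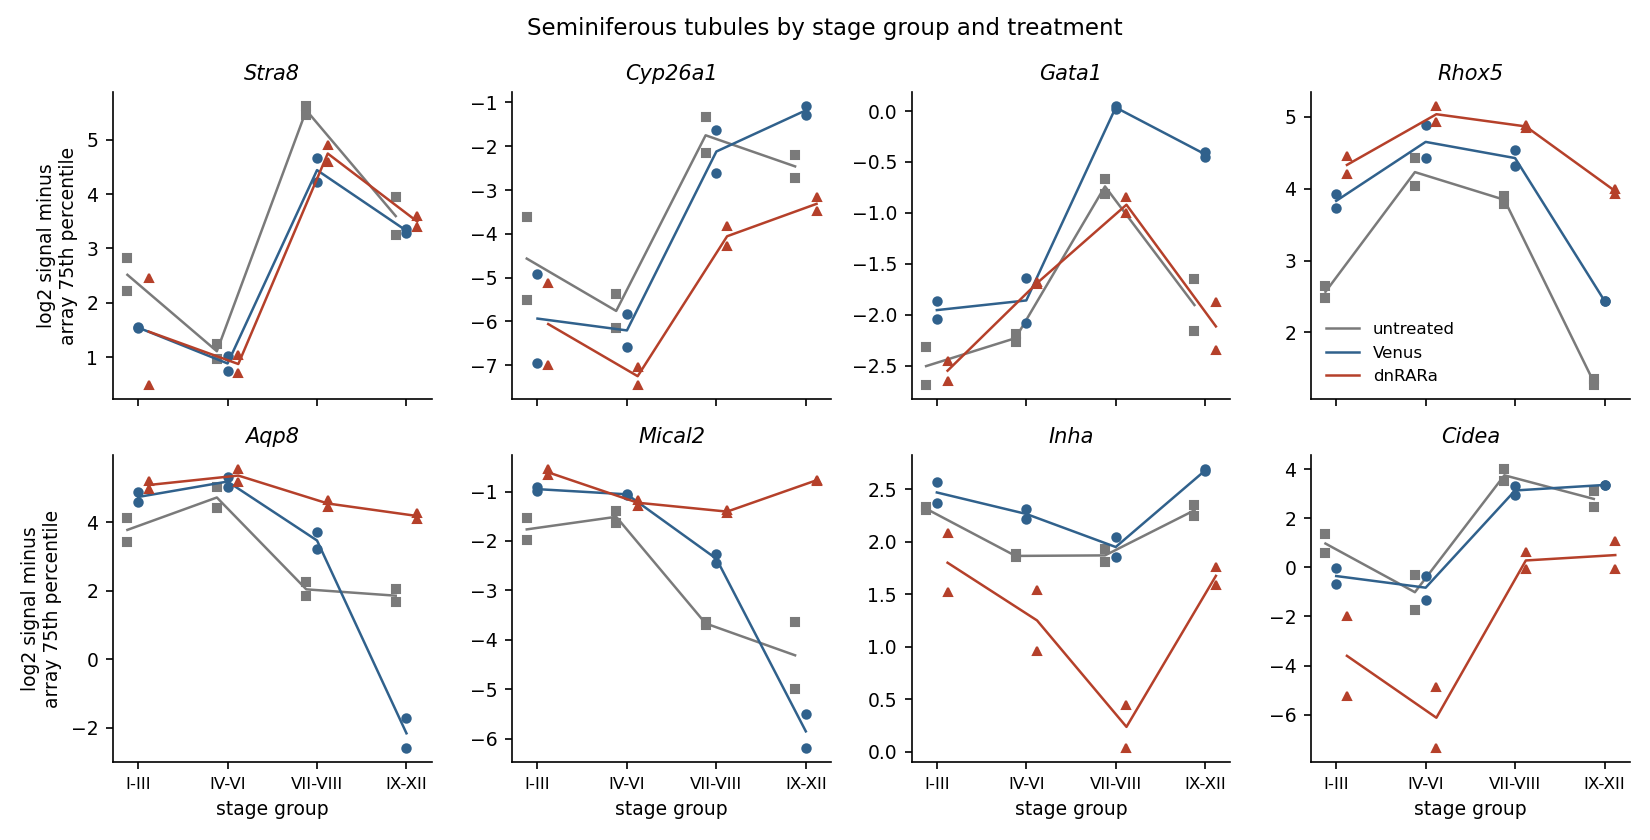
Log2 signal relative to the array's 75th percentile (vertical axes) of 8 genes over 4 stage groups (horizontal axes) in untreated (grey squares), Venus (blue circles) and dnRARa (red triangles) tubules; points are the 2 arrays of a group and lines join their means. In stages IX-XII Aqp8 stood at -2.16 with Venus and 4.18 with dnRARa, and Inha in VII-VIII at 1.95 and 0.23.

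The interaction asked whether the difference between later and earlier stages itself differed between dnRARa and Venus tubules. For Aqp8 the stage difference was -4.31 with Venus and -0.86 with dnRARa, so the interaction was 3.45 (SE 0.31, adjusted p = 0.000309), and for Mical2 it was 2.94 (SE 0.31). For Mpzl2, Ptpn7 and Chst8 it was 2.7, 2.53 and 2.4. Elovl3 passed too, but neither Venus array of IX-XII was above background, so no size is given. Lower values, from -2.07 to -1.41, were found for Runx2, Anxa9, Hpca, Tnfrsf21 and Tec. Gata1 (-1.11, SE 0.2) and Plat (-1.17, SE 0.21) rose less toward the later stages with dnRARa, while the late spermatid genes Tnp2 (1.73, SE 0.34) and Prm1 (1.08, SE 0.24) had higher values. For Stra8 (0.28), Rara (0.25), Nanos3, Sox9 and Cldn11 no difference passed (adjusted p = 0.867 for Stra8 and 0.81 for Rara). Cyp26a1 and Rarb lay at background in some of the stage groups, so their interaction was not measured. In untreated tubules, on other slides and days, the stage difference of Mpzl2 was -0.59, against -3.03 with Venus and -0.32 with dnRARa. That of Runx2 was 1.56, against 3.38 and 1.31, and that of Hpca 1.04, against 2.44 and 0.84. For Ptpn7 (-3.92, against -4.57 and -2.04) and Tnp2 (1.35, against 1.07 and 2.8) it lay nearer the Venus value. The interaction alone therefore does not tell which arm departed from untreated tubules.

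Cell cycle genes were called higher (median 0.27, 1 of 21 passing, Aurka, and 8 over the list alone; adjusted p = 0.000838, and adjusted p = 0.422 with an estimated correlation), with slide medians of 0.19 and 0.27. The Leydig list was called lower with none of 10 genes passing, over all genes or over the list alone (adjusted p = 0.00837, and adjusted p = 0.985 with an estimated correlation). Of 24116 genes 239 passed, 157 higher and 82 lower; these were chosen by the interaction itself. The stage difference could be estimated in both arms for 236 of them, and its size was smaller with dnRARa in 173 and larger in 63. It had passed in Venus tubules for 202 of the 236, of which 21 passed in the opposite direction with dnRARa. Which arm departed from untreated tubules was not assessed for these genes as a set. The count was 320 with slide and 290 with scan day as a block. Within the replicate 1 and replicate 2 slides alone limma called 0 and 0, with 453 and 347 genes at an unadjusted p under 0.05. These models, with 4 residual degrees of freedom, also had no terms for single stage groups, so fewer genes could pass. The interaction estimates of both days correlated across genes at r = 0.385 (rho 0.382). Leaving out 1 array gave 31 to 316 and normexp 36, with an all-gene median of -0.084 in place of 0.052.

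Venus tubules were compared with untreated ones to measure what injection and a control virus changed. Markers of macrophages were higher, the complement genes C1qa by 2.22 (SE 0.15), C1qb by 1.44 (SE 0.1) and C1qc by 2.24 (SE 0.16) and the lysozyme gene Lyz2 by 1.47 (SE 0.15). Sox9 was 0.89 higher (SE 0.11), Cldn11 0.25 (SE 0.06) and Rhox5 0.85 (SE 0.08), and Stra8 was lower (-0.64, SE 0.22, adjusted p = 0.018), while Cyp26a1 (-0.23) and Nanos3 (-1.63) did not pass (adjusted p = 0.597 and 0.108). The retinol receptor gene Stra6 was lower (-3.65, SE 0.3) and Dhrs3 was higher (1.14, SE 0.14). Rara rose at least 1.03-fold above background, but its difference was -0.52 under normexp. The largest rises were of Afm (at least 31.6-fold), Agr3, Cstdc3, Speer9-ps1, Kcnip4 and Nnmt, and the largest falls of Cck (at least 230-fold), Defa23, Abra, Pramel39, Dusp16 and Klf1.

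Of 13 macrophage and immune genes 9 rose and 2 fell, of 21 lysosome genes 16 rose and 1 fell, of 23 Sertoli genes 19 rose, of 9 peritubular myoid genes 8 rose and of 8 androgen-responsive genes 7 rose. Camera called all 5 lists (adjusted p = 0.66, 0.609, 0.384, 0.483 and 0.483 with an estimated correlation, against 0.0321, 0.00698, 0.000294, 0.00698 and 0.00698 with the preset value). The same counts held over the lists alone. Under normexp the macrophage median fell from 1.13 to 0.23 and the Sertoli median from 0.57 to 0.24, while those of the lysosome, peritubular and androgen-responsive lists went from 0.65, 0.79 and 0.72 to 0.48, 0.72 and 0.63. Over 4 scalings as few as 5 macrophage genes were higher and as many as 4 lower, and as few as 12 Sertoli genes were higher. Of 18 interferon genes 10 rose and 1 fell, but the median turned from 0.6 to -0.27 under normexp and as few as 2 rose over 4 scalings. In all 15889 of 23740 genes passed, 8618 higher and 7271 lower, and the share higher among them, 54.2%, was 30% with normexp, which moved the all-gene median from 0.059 to -0.323. The arms lay on different slides and days throughout, so the effect of injection and virus cannot be told apart from batch.

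Across genes, which are not independent replicates, the dnRARa difference was set against the stage difference of untreated tubules and the RA response in culture. Over 4977 sorted-enriched genes the dnRARa difference ran against the untreated stage difference (r = -0.236, rho = -0.159): 172 genes higher in later stages were lower with dnRARa, where independent lists would give 81.8, and 123 were lower in later stages and higher with dnRARa (71.8). Over all 19379 tested genes r was -0.075 (rho = -0.035). Against the RA response r was -0.201 (rho = -0.149) over 5867 sorted-enriched genes and -0.132 (rho = -0.047) over all 19186 tested genes. Of the sorted-enriched genes 79 raised by RA were lower with dnRARa (18.8 for independent lists) and 7 were higher (16). Tnfsf13, Ccdc69, Mgarp and Mmp15, chosen after their values were seen, were raised by RA by 2.34, 2.12, 1.87 and 2.99 and differed by -1.42, -1.29, -1.29 and -1.18 with dnRARa. No arrays are shared between the measures paired here; the sorted-enriched genes include Leydig and endothelial markers such as Insl3 and Cdh5.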

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

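The tests of the 3 patterns weighed here were chosen after the results were seen, while the counts over other splits of the arrays were planned.

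The difference between stages VII-XII and I-VI differed between dnRARa and Venus tubules, by a test of the interaction itself, in 239 genes. Among named genes the interaction was 3.45 for Aqp8, 2.94 for Mical2, 2.7 for Mpzl2, 2.53 for Ptpn7 and 2.4 for Chst8. The fitted value for Elovl3, 2.2, is no measured difference, since neither Venus array of IX-XII was above background. The interaction was -2.07 for Runx2, -1.84 for Anxa9, -1.6 for Hpca, -1.47 for Tnfrsf21 and -1.41 for Tec. From the lists it was 1.73 for Tnp2, 1.4 for Alas2, 1.08 for Prm1, 0.81 for Aurka, 0.61 for Ctnna1, -1.11 for Gata1 and -1.17 for Plat. The untreated stage difference lay nearer the dnRARa value for some of these genes, such as Mpzl2 and Runx2. For others, such as Ptpn7 and Tnp2, it lay nearer the Venus value.

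Other splits of the same arrays show how often an arbitrary grouping gives as many genes. Counts here come from models of only the arrays split, without stage group terms for the stage differences, so they differ from those of the full model. For the stage difference in untreated tubules the real split gave 2583 genes and the highest other 2391, which set I-III and IX-XII against the remaining stages; 1 of 35 splits, the real one, gave as many. In Venus tubules the values were 7248 and 0 (limma) and in dnRARa tubules 4253 and 1717, again with 1 of 35 splits as large. For dnRARa against Venus they were 4638 and 1734 and for Venus against untreated 15463 and 9677, with 1 of 100 splits as large in each. For the interaction the real split gave 978, and 3 of 100 splits gave as many, the real one included. The highest gave 4638, several times the real count, because it exchanged the arms of whole stage groups and so measured the mean dnRARa difference. The 4 drawn splits that kept the replicates together in every stage group gave 8 to 4638 (median 862.5). All other drawn splits gave at most 708, so both splits as large as the real one were among these 4. The share of splits as large was under the planned 0.05 for each of the comparisons above. Splits that part the replicates of a group add group differences to the residual spread, so fewer genes can pass in them. The share therefore cannot exclude chance. Arrays of a slide or stage group are also not independent: those of the dnRARa arm correlated by replicate at 0.44 to 0.7 between stage groups. Whole slides of dnRARa and Venus tubules can be grouped in only 3 ways, too few for a share under 0.05; limma called 4638 genes for the real grouping and 0 for the other two, and 978 and 0 for the interaction. Of the 35 stage splits 32 broke up stage groups, which leaves 3 of whole stage groups, again too few.

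Leydig transcripts were higher in sorted WT Sertoli cells than in whole testes, with a list median of 4.26. Its members of highest signal, Insl3 and Agt, were at 9.71 and 9.1 in the sorted cells. Of the 11 genes 9, all but Lhcgr and Cyp21a1, were above background in whole testes too. No other list holds a member of this list. Against loss of germ cell transcripts alone, the Leydig median exceeded that of the Sertoli list by 3.49, where the Sertoli list's interquartile range was 1.49, and against scaling, the lowest median over 4 scalings was 3.8. A candidate explanation is Leydig cells among the cells sorted by FACS, whose marker the labels do not give; the list's median in cultured against sorted cells, which shares the sorted arrays, was -7.84. For the Leydig pattern no biological explanation was tested.

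Differences between dnRARa and Venus tubules lay on separate slides. Against differences between slides as the whole cause, fold changes from the replicate 1 and replicate 2 slides correlated across genes at r = 0.515. Blocked RA receptor signaling may account for part of the pattern: 79 sorted-enriched genes raised by RA in culture were lower with dnRARa, where independent lists would give 18.8. The RA target list ran lower without being called (camera adjusted p = 0.163), and Stra8, which RA raised in culture, did not pass. Peritubular myoid genes were lower too, with list medians of -0.72 and -0.3 on the replicate 1 and replicate 2 slides. The sorted-enriched genes include markers of other somatic cells. Array differences shared by both dnRARa slides stay open.

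Aqp8 was higher with dnRARa than with Venus in stages IX-XII. A single pair of slides as the source is argued against by differences of 6.69 and 6.01 on the replicate 1 and replicate 2 slides. Tubules of stages I-VI among those collected as IX-XII would have to make up 57.4%, and 389 genes low in untreated IX-XII tubules would then rise by a median of 2.34; the observed median was 0.48 (interquartile range 1.1), so a smaller mixture stays open. In the 274 testis-enriched genes among them the medians were 2.53 and 0.37 (interquartile range 1.14), but in the 32 sorted-enriched ones they were 1.75 and 0.69, a gap within the interquartile range of 1.1. Lowering of Aqp8 by RA cannot be told apart from no effect, since in cultured cells its RA difference was -1.12 (SE 0.63, adjusted p = 0.442). The Venus mean of Aqp8 in IX-XII, -2.16, lay below the untreated mean of 1.86.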

How the results depend on the processing

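The normexp correction of the median signal and the fits within single slides or days were chosen after the data were seen; the other alternatives were planned. Of 363 alternatives for counts and summary values 268 left the value within the limit, 95 moved it beyond and 0 reversed it. A reversal could be scored only for the correlation of the untreated stage and dnRARa differences, since a count has no sign. Changes in the balance of higher and lower genes were not scored. For Venus against untreated, 8618 higher and 7271 lower became 4786 and 11147 with normexp. The limit was 1.5 times for counts, and for the correlation the SD of its values with 1 array left out, 0.0174. Of 16813 alternative values of named genes 15700 kept direction and side of the threshold, 1057 were weaker, 33 stronger and 23 reversed. The 363 and the 16813 both include a rerun on the deposited series values. These equal the processed signal, so that rerun, 826 of the 16813 values, could not differ. The cause was not tested for any change listed here, except that a 2-fold minimum lowers counts by construction.

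With normexp the counts were 562 for RA, 7125 and 6364 for the Venus and dnRARa stage differences, 731 for dnRARa against Venus, 0 (limma, 437 at an unadjusted p under 0.05), 150, 59 and 260 in its stage groups from I-III to IX-XII, and 36 for the interaction. In I-III quantile and median scaling gave 1 and 1, and 1 model for all 34 arrays 36. Models of only the arrays compared gave 4174 for knockout against WT, 7196 for RA, 4648 for dnRARa against Venus, 0 (limma, 2296 unadjusted) in I-III, 1 in IV-VI, 0 (2658 unadjusted) in VII-VIII and 974 for the interaction. An intensity trend gave 0 in I-III (limma, 1538 unadjusted) and 436 for the interaction. Without a detection filter counts were 714 for RA, 286 in IV-VI, 718 in IX-XII, 80 for the interaction and 23836 for Venus against untreated, and with detection on all arrays 390 for the interaction.

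A 2-fold minimum gave 5738 for knockout against WT, 616 for RA, 2701, 3496 and 3048 for the untreated, Venus and dnRARa stage differences, 406 for dnRARa against Venus, 321 in IV-VI, 527 in IX-XII, 120 for the interaction and 3825 for Venus against untreated. With the replicate block counts were 31 in I-III, 558 in VII-VIII and 386 for the interaction, and 910 for the latter with replicate within arm; replicate within stage gave 1 in I-III. The replicate block left RA at 872, knockout against WT at 10074, untreated stages at 10550, dnRARa against Venus at 3908 and Venus against untreated at 16414. The scan-day block gave 26 in I-III. Within replicate 1 and replicate 2 slides counts were 765 and 1615 for dnRARa against Venus, 0 and 0 for the interaction (limma, 453 and 347 unadjusted), 419 and 62 for Venus stages and 0 and 0 for dnRARa stages (limma, 2908 and 3654 unadjusted). The interaction and stage models among these had no terms for single stage groups, so fewer genes could pass in them.

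Leaving out 1 array, where a lone array is assumed to vary like the other groups, gave 363 to 381 for RA, 17 to 265 in I-III (265 without dnRARa replicate 1), 38 to 737 in IV-VI, 84 to 535 in VII-VIII, 322 to 629 in IX-XII and 31 to 316 for the interaction. Any 1 of the 4 arrays moved RA, I-III, VII-VIII and IX-XII, 3 of 4 moved IV-VI and 13 of 16 the interaction. The range was -0.256 to -0.189 for the correlation of the untreated stage and dnRARa differences. That correlation was -0.298 with normexp, -0.26 with detection on all arrays and -0.075 over all tested genes. With an estimated correlation 1 list call was left.

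Reversed with normexp were Nanos3 in knockout against WT (0.13), Dsg2 with RA (-0.27), Tek (0.09), Crabp1 (0.04) and Tnc (0.32) in untreated stages, Cxadr in Venus stages (0.02), Gpr149 in VII-VIII (0.19), and Gdnf (-0.55) and Tnc (-0.31) in IX-XII. For Venus against untreated they were Rara (-0.52), Gdnf (-0.68), Sall4 (-0.02), Neurog3 (-0.52), Cyp21a1 (-0.87), Cdh5 (-0.22), Slc4a1 (-0.12), Irf7 (-0.22) and Col5a2 (-0.27). Sparc in knockout against WT was 0.04 with median scaling, and Slc4a1 in cultured against sorted cells 0.52 with quantile and 0.09 with median scaling. With the mean over probes Ifih1 in knockout against WT was -0.83 and Hormad1 in dnRARa stages 0.07.

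Not run were slide and day blocks for the cell comparisons, and a day block for untreated stages and for Venus against untreated, where day is shared or follows the groups; normexp on the mean signal lacked its column. Genes not well above background on both arrays of any group compared were not tested.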

Other observations

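The genes and the comparison described here were chosen after the values were seen.

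Untreated tubules of stages VII-VIII and IX-XII shared 1 slide and were compared with each other. Prnd was 5.09 higher (SE 0.32) and Tbc1d23 4.97 higher (SE 0.45) in VII-VIII, and Rhox5 was 2.54 higher (SE 0.16), as were the acrosomal genes Spaca1 (3.26) and Izumo1 (3.73). Higher in IX-XII were the meiotic cyclin gene Ccna1 (-3.57, SE 0.19), Aurkb (-4.24, SE 0.24), Plk1 (-3.75, SE 0.17) and Espn (-2.43, SE 0.15). Of 21 cell cycle genes 5 were higher and 11 lower in VII-VIII. In limma 9418 of 18892 genes passed, 4658 higher and 4760 lower in VII-VIII.

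Among genes with several probes tested, probes with opposite calls were found for 600 of 4358 genes in sorted cells against testes. It was 349 of 4165 for knockout against WT cells, 366 of 4437 for cultured against sorted cells and 0 of 4202 for RA. For later against earlier stages it was 235 of 3800 in untreated, 265 of 4563 in Venus and 217 of 4505 in dnRARa tubules. For dnRARa against Venus it was 14 of 4611, for the interaction 0 of 4611 and for Venus against untreated 741 of 4576.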
